A study of Homo sapiens with 8 samples.

How the data were processed

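The series holds 8 droplet libraries (10x Genomics, 3' end kit) of astrocytes differentiated from the stem cell lines 1016A (3 libraries), Hues8 (3) and H1 (2), grown in a commercial astrocyte medium without treatment, per the labels. Each deposited file held UMI counts per gene and cell barcode, as whole numbers that were not normalized. Per the file headers, the counts were made with the Drop-seq tools against a combined human and mouse reference, from reads with a mapping quality of at least 10 on the sense strand of coding, untranslated and intronic sequence. Barcodes of molecules within an edit distance of 1 were merged, background was removed with CellBender, and barcodes were selected, per the file headers. The submitters' processing notes name GRCh38 and Seurat 4.0.2. The aligner is not given in the sources used here. The mapping quality minimum removes reads that fit near-identical genes equally well, and background removal can lower genes of few counts. Human gene names were used as the files give them, 34056 over the 8 files.

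A barcode was kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrially encoded genes. Of 70619 barcodes, 86 had too few UMIs, 163 too few genes and 6103 too many mitochondrial UMIs, and 64411 were kept. Scrublet marked 2 cells, or 0.00311%, as doublets, which is too few for the caller to have worked, so no doublets were removed and removal of called doublets was not run. In its place the 5% of cells with the most UMIs in each library were left out as an alternative chosen after seeing the data.

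Counts were summed over the kept cells of each library, since cells are not replicates. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood F test) with 1 coefficient per line over all 8 libraries, so that the lines share 1 estimate of the spread, on 25148 genes. Log2 fold changes are given with standard errors from the F statistic and p-values adjusted by Benjamini-Hochberg, with a threshold of 0.05. The series calls libraries of a line biological replicates but names no separate differentiations, so the p-values measure the spread between these libraries. Their biological coefficient of variation was 48.7%. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. There were 34 lists, 13 of them of cell type markers, with at least 3 tested members each. Of their 505 genes, 8 were absent from the tables and not analysed here, C1QC, C2, C6 and VSIG4 of the complement list among them. Of 136 list results, the median, mean and camera direction differed in sign in 22, none of which passed.

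The genes named are, per comparison, up to 8 in each direction with the largest log2 fold change among those that passed, had no overlap between libraries of the groups and at least 20 CPM in the higher group, then up to 4 passing members of each list, then 12 complement and astrocyte genes and C4 whatever their result. Clone-named transcripts and sex-linked genes XIST, TSIX and those on the Y chromosome were left out. The lists, this rule and the designs were fixed before the data were examined. IFI27, COL1A1 and the genes of single libraries were chosen after their values were seen. Some genes that the rule names are not reported here.

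Cells were clustered with scanpy 1.11.5 and igraph 0.11.9 on log values of 2000 variable genes, scaled within each library (30 components, 15 neighbours, Leiden resolution 0.5). Clusters were named from at least 3 markers, and a name was chosen after the raised markers of each list were seen. The leading genes of each cluster were ranked by fold over the other cells with 10 CPM added, among genes seen in at least 10% of the cluster. Shares of cells were compared between 1016A and Hues8 with two-sided exact permutation tests. C4 shares were taken after thinning to 2000 UMIs per cell, which left out 122 cells of H1 replicate 1 and 0 of the other libraries. Intervals are exact at 95%, and a count of 0 is given as up to 3 counts.

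The gene and list tests were tested on simulated counts of 24706 genes drawn with these libraries' means, sizes and dispersion, with 200 genes changed. For 1016A against Hues8, 43% of 4-fold changes and 1% of 2-fold changes were called, with median recovered log2 values of 1.96 and 1.08. For 1016A against the embryonic lines they were 57% and 2%, with 1.98 and 1.02. The list that was moved was called in both, with 0 other lists. Each gene was drawn independently of the others, so the simulation cannot show how the list test behaves with correlated genes. At a dispersion of 0.01 all changed genes were called.

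Alternatives were DESeq2 1.42.0, RLE scaling, glmTreat against a log2 fold change of 1, no filter on low counts, a term for the replicate number, a term for the kind of file name (4 names carry a suffix and 4 do not), only the lines compared, all barcodes, at least 1000 genes with at most 5% mitochondrial UMIs, cells without cycle gene UMIs, libraries thinned to 1 total, other cluster settings and each library left out. The C4 test was also run with C4A and C4B alone. Fits over cells of 12000 to 20000 UMIs, whose library medians lie between 14488.5 and 17361 UMIs, and fits without cluster 4, the cluster led by ANKRD1, were chosen after seeing the data. Within a kind of file name a line has 1 or 2 libraries, so a test within each kind was not made. Gene positions come from GENCODE release 29 on GRCh38.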

Results

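Single-cell RNA sequencing was used to profile astrocytes differentiated from 3 human pluripotent stem cell lines in 8 untreated libraries. 1016A is an induced pluripotent line and contributed 3 libraries. Hues8 and H1 are embryonic stem cell lines and contributed 3 and 2 libraries. The series concerns the secretion of C4, a complement protein, so the RNA of C4 and of the other complement genes was measured first, followed by the differences between the lines. The files held 70619 cell barcodes, and 64411 were kept, from 4584 in Hues8 replicate 2 to 14127 in H1 replicate 1. The kept cells of a library held between 149542470 and 205119064 unique molecular identifiers (UMIs). The median per cell ranged from 10867 UMIs in H1 replicate 1 to 28427.5 in 1016A replicate 2.

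The cells of every library were rich in collagen RNA, and held little RNA of the astrocyte markers GFAP and AQP4. COL1A1, a fibrillar collagen gene, lay between 4820 and 8724 CPM (UMIs of a gene scaled to the total of its library). GFAP, an intermediate filament of astrocytes, did not exceed 3.35 CPM in any library, and AQP4, the astrocyte water channel, did not exceed 0.0809 CPM. VIM, another intermediate filament gene, had a mean of 4984 ± 1093 CPM in 1016A (SD, n = 3), 6302 ± 622 in Hues8 (SD, n = 3) and 4672 CPM in H1 (n = 2). Other astrocyte markers were higher. SLC1A3, a glutamate transporter, had 94.0 ± 72.8 CPM in 1016A (SD, n = 3), 131 ± 84.9 in Hues8 (SD, n = 3) and 146 in H1 (n = 2), and S100B, a calcium-binding protein, 28.7 ± 46.8, 10.97 ± 18.6 and 0.831 CPM. The kept cells fell into 19 clusters, and 82.2% of the cells lay in clusters without a name. No cluster was named astrocyte-like, since each of the 4 with at least 3 of the 20 astrocyte markers raised by over 1 log2 unit had as many or more raised from another list of cell type markers. Markers were scored against all other cells, so an identity that most cells share cannot raise them in any cluster. The missing name and the share of cells without a name therefore do not show which identity these cells had.

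The neural progenitor-like and muscle-like classes each came mostly from 2 libraries of different lines. A cluster led by FABP7, A2M, S100B, PTN and PTPRZ1 had 7 of 15 markers of radial glia and neural progenitors raised by over 1 log2 unit, with a mean log2 fold of 1.42 over the list, and 7 of 20 astrocyte markers, with a mean of 0.83. It held 17.7% of the cells of Hues8 replicate 1 and 17.4% of those of 1016A replicate 2, and at most 2.44% elsewhere. Cells led by ACTC1, MYLPF, TTN and other sarcomere genes were muscle-like, and made up 7.71% of H1 replicate 1 and 8.54% of 1016A replicate 2 but at most 0.0889% of any other library. Cycling cells, led by TOP2A, CENPF and MKI67, made up 11.3 ± 5.77% of 1016A (SD, n = 3), 18.9 ± 4.35% of Hues8 (SD, n = 3) and 5.11% of H1 (n = 2). The Hues8 libraries lay between 14.02 and 22.4% and the H1 libraries at 3.33 and 6.88%. The neural progenitor-like cluster also had all 30 cell cycle genes raised by over 1 log2 unit (mean log2 fold 1.73, against 2.41 in the cycling cluster), so cycling cells in it are not in these shares. No class passed between 1016A and Hues8, with adjusted p between 0.8 and 0.9 in two-sided exact permutation tests, which cannot go below 0.1 with 3 libraries against 3. Only 1 of the 19 clusters had 1016A and Hues8 libraries that did not overlap, where chance separates 10% of clusters. Values were scaled within each library before clustering, and more clusters separated with scaling over all cells or at resolution 1.0. Of the 19 clusters, 14 drew over 50% of their cells from 1 library.

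**Figure D1:**
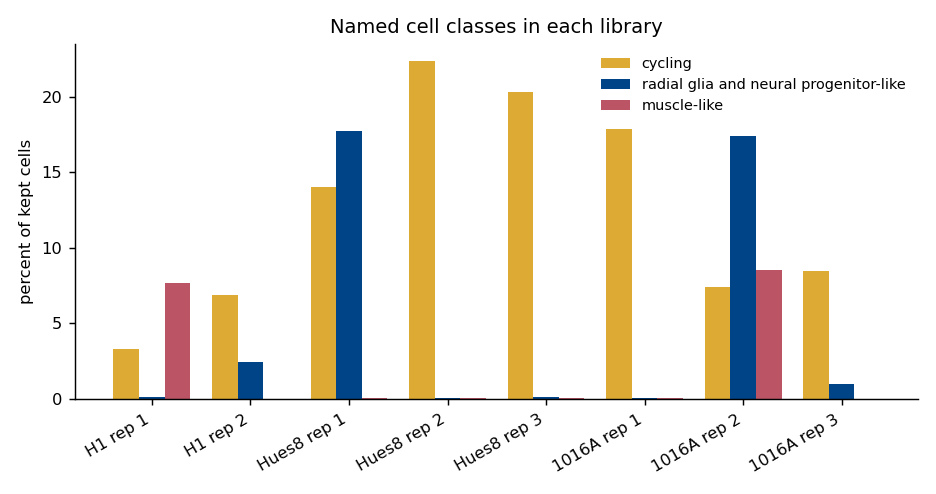
Percent of kept cells in each named class (bars, vertical axis) for each of the 8 libraries (horizontal axis). The neural progenitor-like class reaches 17.7% in Hues8 replicate 1 and 17.4% in 1016A replicate 2, and the muscle-like class 7.71% in H1 replicate 1 and 8.54% in 1016A replicate 2.

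C4 RNA was close to the limit of detection in every line. The genes C4A and C4B are near-identical copies on chromosome 6 (GRCh38, 31982024 to 32002681 and 32014795 to 32035418, both on the plus strand), so their counts were added. The sum was 29 UMIs over all 8 libraries: 17 in H1 replicate 1, 5 in H1 replicate 2, 2, 1 and 1 in the Hues8 libraries and 0, 3 and 0 in the 1016A libraries. Of these, C4B had 15 and 5 in the H1 libraries, 0 in each Hues8 library and 2 in 1016A replicate 2. The remaining UMIs were assigned to C4A. These counts are too few to compare the copies. H1 replicate 1 had 0.0917 CPM, with an exact Poisson 95% interval of 0.0534 to 0.147 that covers counting error only. The 2 1016A libraries with 0 UMIs allow up to 0.0174 and 0.0146 CPM, the level of 3 counts. Since the Hues8 and 1016A libraries lay at or under this floor, no fold change between them is given, and log2(CPM + 1) did not differ in a two-sided exact permutation test (p = 1, n = 3 and 3). C4 did not pass the minimum count filter of the gene test. Entered in spite of it, C4 gave edgeR adjusted p = 0.895 for 1016A against Hues8, 0.36 for 1016A against H1 and 0.187 for Hues8 against H1. In the same order the unadjusted edgeR p was 0.722, 0.0283 and 0.0469. With so few UMIs these values do not establish a difference of H1 from the other lines. After each cell was thinned to 2000 UMIs, at most 3 cells of a library kept a C4 UMI, and only 29 cells had one before thinning. Cells with and without C4 RNA were therefore not compared, and the share of cells was read neither as expression nor as a difference between lines.

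Of the other complement genes, 19 passed the minimum count filter, and their median was at least 2.47 CPM in every library. C1R, whose protein activates C1s, and C1S, whose protein cleaves C4, had means of 43.3 and 40.0 CPM in H1 (n = 2), 12.6 ± 10.1 and 14.4 ± 7.45 CPM in 1016A (SD, n = 3) and 3.68 ± 1.35 and 9.04 ± 1.04 CPM in Hues8 (SD, n = 3). C3, the central component of the complement system, had 1.24, 1.56 and 0.154 CPM in H1, 1016A and Hues8. None of C1R, C1S and C3 passed in any comparison of lines, with edgeR adjusted p of at least 0.0604.

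**Figure D2:**
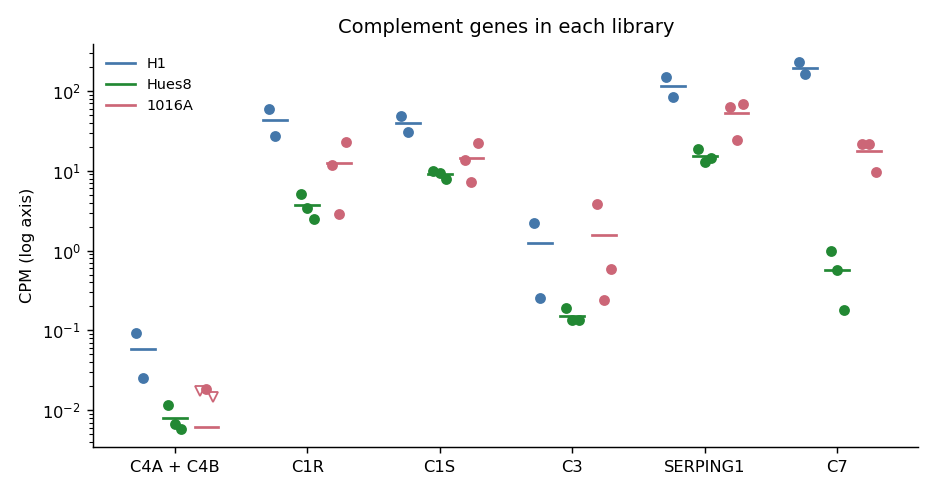
Complement genes in CPM on a log axis (vertical) by gene (horizontal), with a point per library and a line at the mean of each cell line. Open triangles mark libraries with 0 C4 UMIs at the level of 3 counts. C7 and SERPING1 lie higher in both H1 libraries than in the 3 Hues8 libraries.

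The comparison of 1016A with Hues8 sets the induced line against the embryonic line with as many libraries. FDXR and DDB2, both regulated by p53, were lower in 1016A, and the complement gene C7 was higher. The p53 and senescence and the cholesterol synthesis lists were called lower and the interferon response list higher with the preset correlation of camera, and none of them with an estimated correlation (adjusted p = 0.389 for p53 and 0.772 for the other 2). FDXR, a p53 target encoding a mitochondrial reductase, had 2.07 ± 0.251 CPM in 1016A and 13.5 ± 2.12 CPM in Hues8 (SD, n = 3 each; log2 fold change -2.73, SE 0.18, edgeR adjusted p = 0.00366). DDB2, a p53-regulated DNA damage recognition gene, had 6.58 ± 2.33 against 32.5 ± 1.91 CPM (log2 fold change -2.32, SE 0.27, edgeR adjusted p = 0.028). C7, a component of the membrane attack complex, had 17.6 ± 7.01 CPM in 1016A and 0.576 ± 0.398 CPM in Hues8 (log2 fold change 4.93, SE 0.62, edgeR adjusted p = 0.0313).

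In all, 119 of 25148 genes differed between 1016A and Hues8, 59 higher and 60 lower in 1016A. The largest differences upward were in the noncoding gene C5orf17, with 38.6 ± 6.46 against 0.0764 ± 0.0214 CPM (log2 fold change 8.97, edgeR adjusted p = 0.000161), and in SLC7A14, FNDC5 and CLDN11, with log2 fold changes of 5.67, 5.34 and 4.21. CLDN11 encodes a tight junction claudin. ZNF667-AS1, SNHG7, ELP5 and NBPF14 followed, with log2 fold changes between 1.38 and 2.05. The largest differences downward were in MTRNR2L1, with 0.0699 ± 0.0079 against 42.1 ± 7.16 CPM (log2 fold change -9.22, edgeR adjusted p = 2.46e-05), and in PTCHD4, PTPRE and MICA, with log2 fold changes of -6.31, -2.93 and -2.54. CNIH3, an auxiliary subunit of AMPA receptors, had -1.97. Values of MTRNR2L1 and NBPF14 are uncertain because near-identical copies exist, the mitochondrial 16S rRNA gene in the case of MTRNR2L1, and those of MICA because its sequence varies between people.

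Of 34 gene lists, 7 differed between 1016A and Hues8. The p53 and senescence list was lower in 1016A (median log2 fold change -1.54, camera adjusted p = 5.75e-12). FDXR and PHLDA3 passed among its 16 measured members, 14 did not, and 13 were lower when adjusted over the list alone. All 20 cholesterol synthesis genes had lower values (median -0.60, camera adjusted p = 1.98e-06), of which 0 passed over all genes and 2 when adjusted over the list alone. The cell cycle list was lower in 30 of 30 members (median -0.50, camera adjusted p = 2.4e-05), with 0 passing either way. The interferon response list was higher in 24 of 28 members (median 1.90, camera adjusted p = 2.5e-05), with 0 passing over all genes, and 12 higher and 1 lower when adjusted over the list alone. The STAT3 list was higher in 13 of 17 members (median 0.78, camera adjusted p = 0.000635), 7 of them when adjusted over the list alone. The complement list was higher in 15 of 19 members (median 1.02, camera adjusted p = 0.00795), 3 of them when adjusted over the list alone, and 13 mitochondrially encoded genes were lower (median -0.33, camera adjusted p = 0.00795). With an estimated correlation none of the 7 passed camera, at p = 0.0196 and 0.0229 (adjusted p = 0.389) for the p53 and complement lists and adjusted p = 0.772 for the others. Only the p53 and senescence list passed fry, which asks whether the genes of a list move one way on balance (adjusted p = 0.0276). The 27 other lists had camera adjusted p of 0.0675 to 0.991, and no list of cell type markers passed (lowest adjusted p = 0.0971).

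The number of genes called between 1016A and Hues8 was 15 to 101 when 1 library was left out, 47 with a term for the kind of file name, and 9 without Hues8 replicate 1 and 1016A replicate 2, the libraries with most neural progenitor-like cells. C5orf17, FDXR, MICA and MTRNR2L1 passed in every fit without 1 library. Without 1016A replicate 1, which had 853 CPM of IFI27, an interferon-induced gene, where no other library exceeded 9.88, the median of the interferon list was 0.63 (camera adjusted p = 0.00159) and that of cholesterol synthesis -0.32. The cell cycle median was -0.23 without Hues8 replicate 1, -0.27 without 1016A replicate 3 and -0.87 without an unnamed cluster led by ANKRD1, HAPLN1 and PLCB4. Without 1016A replicate 3 the STAT3 median was 0.50 and the complement median 0.67, and without Hues8 replicate 3 the complement median was 0.66. The cluster led by ANKRD1, in which 5 of the 16 members of the p53 and senescence list were raised by over 1 log2 unit, held 27.6% and 44.3% of the cells of Hues8 replicates 2 and 3 and at most 4.91% of any other library. Without this cluster the p53 and senescence list in 1016A and Hues8 had a median of -1.49 (camera adjusted p = 4.24e-10), PHLDA3, PTCHD4 and PTPRE did not pass, and the mitochondrially encoded genes had camera adjusted p = 0.0872. Over cells of 12000 to 20000 UMIs their median was -0.20.

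Against H1, the other embryonic line, the p53 target FDXR was lower in 1016A, and the cell cycle and glycolysis lists were called higher with the preset correlation of camera. With an estimated correlation neither list passed (adjusted p = 0.914 for each). The cell cycle list was higher in 29 of 30 members (median log2 fold change 1.07, camera adjusted p = 2.03e-13), with 0 passing over all genes and 22 when adjusted over the list alone. FDXR again had lower values, 2.07 ± 0.251 CPM in 1016A (SD, n = 3) against 10.7 ± 0.722 in H1 (SD, n = 2; log2 fold change -2.39, SE 0.19, edgeR adjusted p = 0.00884).

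The test called 47 genes, 21 higher and 26 lower in 1016A. Higher were C5orf17 (log2 fold change 7.84, edgeR adjusted p = 0.00104), the esterase gene IAH1 with 56.5 ± 6.19 against 2.69 ± 0.618 CPM (log2 fold change 4.37, edgeR adjusted p = 0.00873), HS3ST3B1, which sulfates heparan sulfate, and ANKRD9 and DCBLD2, with log2 fold changes of 1.48, 1.14 and 1.04. Lower were MTRNR2L1, with a log2 fold change of -9.79, SLC9A9, a sodium and proton exchanger of endosomes, with -2.19, and the mitochondrial cysteine tRNA gene MT-TC with -1.73. SERPING1, the inhibitor of C1R and C1S, had 52.2 ± 24.1 CPM in 1016A and 116 ± 46.9 in H1 and did not pass (edgeR adjusted p = 0.4).

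The test of lists called 8 of 34. Beside cell cycle these were p53 and senescence, lower in 14 of 16 members (median -0.88, camera adjusted p = 0.000122), with FDXR passing and 8 lower when adjusted over the list alone, and 6 lists that were higher. Cholesterol synthesis was higher in 20 of 20 members (median 0.58, camera adjusted p = 0.00048), glycolysis and hypoxia in 20 of 22 (median 0.63, camera adjusted p = 0.000782), interferon response in 23 of 28 (median 1.59, camera adjusted p = 0.00504), the unfolded protein response in 15 of 16 (median 0.41, camera adjusted p = 0.00504), HOX genes in 21 of 25 (median 2.15, camera adjusted p = 0.00806) and MHC class I in 10 of 10 (median 0.72, camera adjusted p = 0.0153). No member of these 6 lists passed over all genes. Each of the 8 had adjusted p = 0.914 with an estimated correlation. MHC class I counts also depend on how reads of each allele align.

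Leaving out 1 library gave 8 to 36 genes, the file name term 18 and cells of 12000 to 20000 UMIs alone 7, and of the 8 lists only cell cycle and glycolysis passed in every fit without 1 library. Camera adjusted p was 0.642 for interferon, 0.411 for the unfolded protein response and 0.886 for MHC class I, whose direction turned, without H1 replicate 1, and 0.167 for cholesterol, 0.334 for p53 and 0.976 for HOX genes, where camera turned and the median stayed at 1.28, without H1 replicate 2; it was 0.685 for interferon (median -0.12) and 0.209 for MHC class I without 1016A replicate 1, and 0.393 for HOX genes (median -0.97) without 1016A replicate 3. Among calls that held, the glycolysis median was 0.36 without 1016A replicate 2 and that of the unfolded protein response 0.21 without 1016A replicate 1. Without H1 replicate 2 the medians of the interferon, unfolded protein response and MHC class I lists were 2.49, 0.69 and 2.20, and without H1 replicate 1 that of HOX genes was 6.90. H1 replicate 1 held muscle-like cells, as did 1016A replicate 2, and had the lowest median UMI count.

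More genes were called between the embryonic lines Hues8 and H1 than between either and 1016A, although the count rested on single libraries. The order turned in some fits, with 91 against 134 for 1016A and Hues8 when only the lines compared were fitted. The complement genes C7 and SERPING1 and the lipid carrier gene APOE were higher in H1. The cell cycle and cholesterol synthesis lists were called higher in Hues8 with the preset correlation of camera, with 7 of 30 and 2 of 20 members passing, and had adjusted p = 0.913 with an estimated correlation. C7 had 0.576 ± 0.398 CPM in Hues8 (SD, n = 3) and 195 ± 47.4 CPM in H1 (SD, n = 2; log2 fold change -8.42, SE 0.73, edgeR adjusted p = 0.0144). SERPING1 had 15.4 ± 2.84 against 116 ± 46.9 CPM (log2 fold change -2.90, SE 0.47, edgeR adjusted p = 0.0405), and APOE, a lipid carrier secreted by astrocytes, 19.2 ± 6.34 against 286 ± 117 CPM (log2 fold change -3.89, SE 0.62, edgeR adjusted p = 0.0399).

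The test called 703 genes, 328 higher and 375 lower in Hues8. Among the largest differences upward were the GTPase gene DIRAS3 (log2 fold change 5.47), the phosphatase gene PTPRE (4.71), the growth factor gene HBEGF (4.19), ADAMTS16 (4.15), POU2F2 (4.12), SEMA7A (4.11) and IAH1 (3.88). Downward they were SULT1E1, an estrogen sulfotransferase, with 0.0958 ± 0.0849 against 179 ± 7.68 CPM (log2 fold change -10.88), CTSF (-8.30), FMO1 (-7.70), EMCN (-7.59), ABCA9 (-7.17) and SLC7A14 (-7.00), with edgeR adjusted p between 0.0136 and 0.0493 over these genes. EDN3, also lower in Hues8 (edgeR adjusted p = 0.0409), had 0.00973 CPM there, below the level of 3 counts, and 29.7 ± 40.2 CPM in H1, so no fold is given. PDGFRA, a receptor of the oligodendrocyte lineage and of mesenchymal cells, had 2.14 ± 0.957 against 92.5 ± 6.34 CPM (log2 fold change -5.42, edgeR adjusted p = 0.0496).

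The test of lists called 8 of 34. The cell cycle list was higher in Hues8 in 30 of 30 members (median 1.49, camera adjusted p = 6.6e-15), with 7 passing, among them TPX2, BUB1, KIF23 and CCNA2 with log2 fold changes of 1.83 to 2.12, and 29 when adjusted over the list alone. Cholesterol synthesis was higher in 20 of 20 members (median 1.15, camera adjusted p = 1.4e-08), with EBP and MVK passing and 16 when adjusted over the list alone. The complement list was lower in 14 of 19 members (median -1.54, camera adjusted p = 0.00392), with C7 and SERPING1 passing and 7 when adjusted over the list alone, and was the list that also passed fry, which asks whether its genes move one way on balance (adjusted p = 0.00833). STAT3 was lower (median -1.03, camera adjusted p = 0.0194), with FOS, CISH and STAT3 passing. Higher were p53 and senescence (median 0.67, camera adjusted p = 0.011), the unfolded protein response (median 0.45, camera adjusted p = 0.0194), MHC class I (median 1.03, camera adjusted p = 0.0322) and TGF-beta (median 0.93, camera adjusted p = 0.04), the last with TGFB1 among its passing members. With an estimated correlation complement had adjusted p = 0.485 and the other 7 adjusted p = 0.913. From lists that did not pass, COL4A1, GBP1 and PGAM1 were higher and EGR1 lower in Hues8, with log2 fold changes of 1.86, 1.67, 1.52 and -1.54.

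No named gene of this comparison passed in every fit without 1 library. The count was 1 without Hues8 replicate 2, 8 without H1 replicate 1, 10 without Hues8 replicate 3, 60 without Hues8 replicate 1, 167 without 1016A replicate 1, 396 without 1016A replicate 2 and 1268 without H1 replicate 2, 190 with the file name term and 1105 without the cluster led by ANKRD1. The cell cycle, cholesterol and complement lists passed in each fit without 1 library, but the complement median was -0.83 without H1 replicate 1. An unnamed cluster led by NEBL and another led by LINC01088, SULT1E1 and CRABP1, with 4 and 7 complement genes raised by over 1 log2 unit, held 67.7% and 13.3% of the cells of H1 replicate 1, 34.8% and 2.25% of those of 1016A replicate 3 and at most 0.781% and 0% elsewhere. Without H1 replicate 1 camera adjusted p was 0.446 for p53, 0.429 for the unfolded protein response, 0.848 for MHC class I and 0.29 for TGF-beta, and without H1 replicate 2 it was 0.244 for STAT3, while the medians of p53 and MHC class I were 1.33 and 2.62. MHC class I had 0.0529 and 0.0777 without Hues8 replicates 2 and 3, the unfolded protein response 0.0897 without Hues8 replicate 3, and TGF-beta 0.0569, 0.053 and 0.0505 without Hues8 replicates 1 and 3 and 1016A replicate 3. In Hues8 and H1 the TGF-beta response list had 0.0679 over cells of 12000 to 20000 UMIs and 0.112 without the cluster led by ANKRD1.

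Setting 1016A against the mean of Hues8 and H1 asks how the induced line differs from their average. With 1 induced line, the origin of the cells and the line cannot be told apart. FDXR and DDB2 were lower in 1016A. FDXR had 2.07 ± 0.251 CPM (SD, n = 3) against 12.4 ± 2.20 CPM in the 5 other libraries (log2 fold change -2.56, SE 0.17, edgeR adjusted p = 0.0037), and DDB2 6.58 ± 2.33 against 29.6 ± 4.48 CPM (log2 fold change -2.14, SE 0.26, edgeR adjusted p = 0.0307).

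The p53 and senescence list had a median log2 fold change of -1.20 (camera adjusted p = 4.28e-13). Of its 16 members 15 had lower values and 1, CDKN2A, a higher value. CDKN2A had 190.9 to 220.9 CPM in 1016A and 12.73 to 196.9 CPM in the other libraries (log2 fold change 0.80, SE 0.70). CDKN2B, counted among the lower members, hardly differed (log2 fold change -0.0075, SE 0.54). The lower value of the list therefore does not extend to CDKN2A and CDKN2B. FDXR was the member that passed over all genes, 15 did not pass, and 12 were lower when adjusted over the list alone. With an estimated correlation the list had p = 0.0166 and adjusted p = 0.563. Against H1 alone its median was -0.30 (camera adjusted p = 0.334) without H1 replicate 2.

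**Figure D3:**
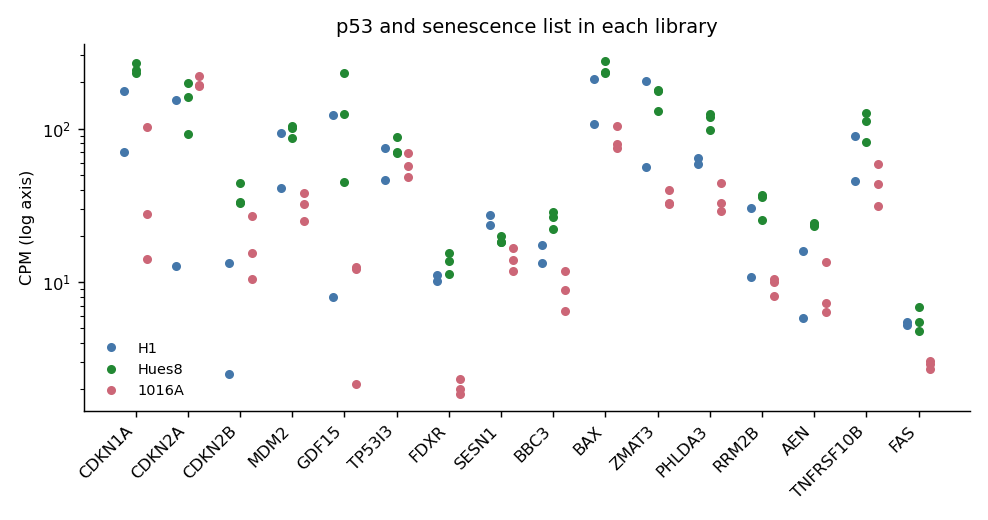
CPM on a log axis (vertical) of each measured member of the p53 and senescence list (horizontal), with a point per library. FDXR lies between 1.85 and 2.34 CPM in the 3 1016A libraries and between 10.2 and 15.5 CPM in the 5 others.

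The test called 77 genes, 46 higher and 31 lower in 1016A. C5orf17 was higher by a log2 fold change of 8.40 (edgeR adjusted p = 6.37e-05), IAH1 by 2.43, ZNF667-AS1 by 1.65, SNHG7 by 1.30 and FAM118A by 1.02. MTRNR2L1 had a log2 fold change of -9.51 (edgeR adjusted p = 1.95e-05), MICA of -1.49 and the antisense gene UBA6-AS1 of -1.30, counted on the sense strand. MICA and IAH1 rested mainly on 1 embryonic line each. MICA had 11.4 to 13.03 CPM in 1016A, 14.96 and 17.7 CPM in H1 and 57.3 to 80.2 CPM in Hues8, and IAH1 had 52.2 to 63.6 CPM in 1016A, 32.1 to 49.2 CPM in Hues8 and 2.26 and 3.13 CPM in H1. Of the lists, 4 others differed. The interferon response list was higher in 28 of 28 members (median 1.82, camera adjusted p = 3.41e-07), glycolysis and hypoxia in 19 of 22 (median 0.55, camera adjusted p = 0.00244) and cell cycle in 26 of 30 (median 0.32, camera adjusted p = 0.0147), and mitochondrially encoded genes were lower in 11 of 13 (median -0.25, camera adjusted p = 0.0195). These 4 had adjusted p = 0.967 with an estimated correlation. The cell cycle value averages opposite directions, since 1016A had lower values than Hues8 in 30 of 30 members (median -0.50) and higher values than H1 in 29 of 30 (median 1.07). The complement list (median 0.04, camera adjusted p = 0.741) and the astrocyte marker list (median 0.05, camera adjusted p = 0.644) did not pass. These medians also average opposite directions, 1.02 against Hues8 and -0.35 against H1 for complement and 0.70 and -0.59 for astrocyte markers. SOX9 and NFIA, transcription factors of the astrocyte lineage, had edgeR adjusted p of 0.983 and 0.893, and CD44, SLC1A3 and S100B had 0.713, 0.881 and 0.758.

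For 1016A and the embryonic lines, leaving out 1 library gave 11 to 43 genes, the file name term 33 and cells of 12000 to 20000 UMIs alone 36, and C5orf17, FDXR and MTRNR2L1 passed in each fit without 1 library. The p53 and interferon lists did too, but without 1016A replicate 1 the median of the interferon list was 0.22 (camera adjusted p = 0.00435). The glycolysis list had camera adjusted p = 0.277 without 1016A replicate 2. The cell cycle list had a median of 0.55 without 1016A replicate 3, and camera adjusted p of 0.371, 0.357, 0.303, 0.0566 and 0.0743 without 1016A replicates 1 and 2, H1 replicate 1 and Hues8 replicates 2 and 3, and mitochondrially encoded genes had 0.09, 0.101 and 0.0566 without 1016A replicate 1, H1 replicate 2 and Hues8 replicate 2. Over cells of 12000 to 20000 UMIs the glycolysis list had 0.289 and the cell cycle list 0.926, where camera turned and the median was 0.04. Without the cluster led by ANKRD1 the cell cycle list had 0.75 and mitochondrially encoded genes 0.119.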

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

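The tests that leave out clusters, Hues8 replicate 1 with 1016A replicate 2, or the cells with the most UMIs, or take cells of 12000 to 20000 UMIs, were chosen only after the results were seen. Of 75 named gene results that passed, 12 passed in every fit without 1 library and 0 reversed, and of 28 list results 14 did. DESeq2, RLE scaling, all barcodes and thinning to 1 total kept 75, 75, 70 and 74 of the 75. The file name term kept 33, the stricter cell filter 51, no filter on low counts 62, cells without a cycle gene UMI 62, glmTreat 22, the replicate block 9, leaving out both Hues8 replicate 1 and 1016A replicate 2 13, and only the lines compared 30 of 63. DESeq2 called more genes, in the order 1016A against Hues8, 1016A against H1, Hues8 against H1 and 1016A against the embryonic lines 1605, 1113, 4443 and 607, with all 119, 47, 703 and 77 edgeR calls among them, and the cause was not tested. Against a log2 fold change of 1, glmTreat called 42, 14, 54 and 43, since it asks for a larger difference. The file name term gave 47, 18, 190 and 33 genes, the stricter cell filter, which keeps 9812 cells, 66, 8, 365 and 25, and leaving out both Hues8 replicate 1 and 1016A replicate 2 gave 9, 2, 59 and 3 genes with 12, 13 and 10 lists in the first, the third and the last comparison. Cells of 12000 to 20000 UMIs gave 7 and 36 genes for 1016A against H1 and the embryonic lines and 3 lists in the last comparison, and kept 54 of the 75 gene and 25 of the 28 list results. Without cluster 4 there were 1105 genes for Hues8 against H1 and 3 lists for 1016A against the embryonic lines, and 70 gene and 24 list results were kept. No filter on low counts gave 455 genes for Hues8 against H1. Without cells with a cycle gene UMI there were 26 genes for 1016A against H1 and 51 for 1016A against the embryonic lines, and with only the lines compared, which leaves fewer samples, 2 for 1016A against H1 and 91 for Hues8 against H1. Where not said otherwise, the cause was not tested. Leaving out 1 library gave 15 to 101, 8 to 36, 1 to 1268 and 11 to 43 genes, and 7 to 11, 5 to 11, 6 to 11 and 3 to 12 lists. A line left with 1 library is assumed to vary like the others. The estimated correlation left 0 lists in each comparison and fry 1, 0, 1 and 0, where camera with the preset correlation called 7, 8, 8 and 5. The MHC class I list in 1016A and H1 reversed without H1 replicate 1 (camera adjusted p = 0.886, range 1.23e-05 to 0.886) and the HOX genes list in 1016A and H1 without H1 replicate 2 (camera adjusted p = 0.976, range 7.18e-08 to 0.976), there with a median that stayed positive. The cell cycle list in 1016A and the embryonic lines reversed over cells of 12000 to 20000 UMIs (camera adjusted p = 0.926), also with a positive median.

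Replicate numbers recur in the lines, although H1 has no replicate 3, and the correlations did not show that a number pairs libraries. The deviations of the 7 pairs with the same number had correlations of -0.371 to 0.182, 2 of them over 0.1, and 0 of 8 libraries correlated best with its own number. Deviations from a line mean sum to 0, so the 2 H1 libraries mirror each other (0.182 and -0.182 with Hues8 replicate 1). The 7 values are therefore not independent and cannot exclude a pairing. With the replicate block the counts were 8, 4, 1 and 3 genes and 8, 9, 12 and 5 lists.

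C4 did not pass in any fit run for it, which were C4A alone, C4B alone, all barcodes, cells without a cycle gene UMI, the replicate block, the file name term, DESeq2 and each library left out, with adjusted p of 0.111 to 0.996 over the 3 pairs of lines. The difference in the share of cells with a C4 UMI, 1016A minus Hues8, was 0.00658 percentage points, 0.0 after thinning to 1000 UMIs, -0.0008 without thinning, -0.01074 without cells with a cycle gene UMI and 0.0 to 0.00987 without 1 library, all from at most 3 cells of a library after thinning. The number of clusters separating 1016A from Hues8 was 1, and 5 at resolution 1.0, 6 with scaling over all cells and 1 to 6 without 1 library. Comparisons of cells with and without a C4 UMI, removal of called doublets and a fit on astrocyte-like clusters were not run, for want of such cells, of a working caller and of a cluster given that name. Thinning every library to 149542470 UMIs kept 74 of the 75 named gene calls, but moved too little to test depth. C4 had at most 17 UMIs in a library, which limits the precision of its values.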

Other observations

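Single libraries carried gene programs that their line did not share, read here after their values were seen. In 1016A replicate 1, a cluster led by IFI27, IFI6, ISG15 and MX1, genes induced by interferon, held 9.80% of the cells against at most 0.742% elsewhere, and ISG15 reached 2011 CPM where the next library had 105 CPM. In 1016A replicate 2, 14.4% of the cells formed a cluster led by EN2, a midbrain and hindbrain patterning gene, and SPP1, and no cell of another library joined it. EN2 had 55.8 CPM in this library and at most 8.22 CPM in the others.

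HOX genes, which mark position along the body axis, also went with libraries. In 1016A replicate 3, HOXB9 had 12.9 CPM and HOXC6 8.75 CPM, while the other 1016A libraries had at most 0.355 CPM of either. Hues8 replicate 1 had 12.3 CPM of HOXB9, and the H1 libraries at most 0.0252 CPM of it. ACTC1, a sarcomere actin gene, had 1271 CPM in 1016A replicate 2, 385 CPM in H1 replicate 1 and at most 4.95 CPM in the others.

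Of the tests that follow, some were chosen only after the result was seen. They were the match of libraries to their line, the ratio of complement genes to C4 and the count of splits over all lists. So were the fits without named clusters or cluster 4 and over cells of 12000 to 20000 UMIs. Some readings were changed after their values were seen. They were those of the match, the estimated correlation, thinning, the ratio of complement genes to C4 and the kind of file name. C4A and C4B were near 0 in every library. In the last 600 bases of a C4A transcript, 100% of 510 windows of 91 bases also occur in a C4B transcript, so removal of reads that fit both genes by the mapping quality minimum is a candidate explanation, although 29 UMIs were counted. The median of the other complement genes was at least 2.47 CPM and at least 75.2 times the upper 95% bound of C4 in every library, which argues against a low level of all complement genes as the whole cause, although a low count of the list may add to it. Low C4 transcription in these cells stays open too.

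The p53 and senescence list was lower in 1016A than in the mean of the embryonic lines. Tables argue against cycling, neural and muscle cells (camera adjusted p = 7.71e-13 without them), cluster 4 (7.38e-12 without it), 1 library (at most 1.32e-07 without 1 library) and depth per cell (7.69e-17 over cells of 12000 to 20000 UMIs) as the whole cause, while thinning to 1 total moved too little to test depth (4.17e-13). Correlation among the members stays open, since p = 0.0166 with the correlation estimated met the bound set beforehand, but that bound left out the choice among 34 lists, and the adjusted p is 0.563. Of 100 splits of the libraries, 2 gave this list a p as small as the real 1.26e-14, the other one with 3.87e-18 and the 1016A libraries kept together, but in 39 of the 100 some list had a p as small, down to 5.59e-33, so chance is not excluded once the choice of the list is counted. A difference between the lines stays open too, and the line and its origin cannot be separated.

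Libraries of 1016A did not resemble each other more than some libraries of different lines. The mean correlation of the deviations of libraries was 0.115 within and -0.222 between lines. Deviations were taken from the mean of all 8 libraries, which makes correlations negative on average. A value of 0 is therefore not the level of unrelated libraries. Pairs with the same kind of file name had a mean of -0.141 and other pairs -0.135. The Hues8 pairs had 0.209 to 0.721 and the H1 pair 0.109, but the 1016A pairs had -0.293, -0.21 and 0.0107. H1 replicate 1 and 1016A replicate 3, of different lines, had 0.305. The gap between the within-line and between-line means changed by -0.02667 over cells of 12000 to 20000 UMIs and by 0.08224 without the named cell classes. These values argue against depth per cell and the named cell classes as the whole cause over all lines, and do not test the 1016A pairs alone. Thinning to 1 total moved nothing (-0.0002085) and tests nothing. Pairs with the same kind of file name differed from other pairs by -0.006622 in mean correlation. Both sets mix pairs within and between lines in unlike shares, so this value cannot decide on the kind of file name, which stays open. Over 50 genes set by the line, 1 of 8 libraries did not match its line's labels, and 0 of the 6 whose line kept at least 2 others, so a wrong label cannot be told apart from a line too thinly sampled to set its genes. Differences between differentiations were not tested and stay open. The same holds for unnamed clusters, which libraries of different lines shared. A cluster led by GREM1 held 29.95% of Hues8 replicate 1 and 30.4% of 1016A replicate 2 (correlation 0.269). The cluster led by NEBL held 67.7% of H1 replicate 1 and 34.8% of 1016A replicate 3. A cluster led by EPHA7 held 44.1% of H1 replicate 2 and 35.9% of 1016A replicate 1 (0.209). Elsewhere these held at most 0.0873%, 0.781% and 15.9%.

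Other splits of the libraries gave fewer genes than the real one. For 1016A against Hues8, 1 of the 10 splits, the real one, gave as many as 119 genes and the highest other gave 0; for lists, 10 of 10 gave as many as the real 7 and the highest other gave 15. These splits are too few for a share under 0.05. For 1016A against the embryonic lines, 1 of 100, the real one, gave as many as 77 genes, with 22 in the highest other. These splits also regrouped the embryonic libraries. A split that kept the 1016A libraries together and regrouped the others gave 21 genes. The count of 77 thus rests on the labels of all lines, and the splits cannot exclude chance for 1016A alone. For lists 96 of 100 gave as many as the real 5, with 15 in the highest other, so chance is not excluded, and with the correlation estimated 0 lists passed in either comparison.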
